A study of Mus musculus with 24 samples.

How the data were processed

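Scanner output of 24 single-colour Agilent mouse 8x60K arrays, labelled with Cy3, was analysed. Per the labels, liver RNA was prepared with the AllPrep kit, 200 ng was labelled with the Quick Amp one-color kit, and B6C3F1 mice were exposed to 4 Gy from a 137Cs source at 0.57 Gy per minute. The processed signal, spot median and local background median are intensity values per the file headers, and the spot marks (well above background, saturated, non-uniform) are 0 or 1. Feature Extraction was version 10.5.1.1 per the file headers and 11.5.1 per the submitters' processing notes. The deposited table holds log2 values that the authors shifted by 1 constant per array and centred on the median of each probe. Their array medians ran from -0.163 to 0.18, they followed the scanner values at correlations of 0.976 to 0.990 with a slope of 1, and they served only as an alternative. Per the file headers the design names mouse build mm9. No coordinates were used.

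Of 59305 spots other than controls, replicate spots were averaged to 55681 probes. Spots that the software marked as non-uniform or as outliers among replicate spots were left out, which removed 94 probes missing on an array; no spot was saturated. Probe accessions were matched to symbols with the RefSeq table of GRCm38.p6. Of 29796 probes with a RefSeq-style accession 28026 (94.1%) matched. Another 27655 probes kept the name in the array file. The processed signal was taken to log2 and the 75th percentile of each array was subtracted. Probes well above background on at least 4 of 24 arrays were kept, and the brightest probe over all arrays stood for each gene. This left 23115 genes, 14954 with a symbol and 8161 under the file's name. Where other probes of a named gene moved the opposite way the gene was not described, except for Cdkn1a, for which 1 other probe gave the opposite sign in both age differences; its age differences are therefore not given.

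Means of 12 cells of age, time and sex, 2 arrays each, were fitted with limma 3.58.1 (lmFit, eBayes; 12 residual and 1.86 prior degrees of freedom) in R 4.3.3, with statmod 1.5.0, jsonlite 2.0.0 and version 1.17.8 of data.table. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Changes were averaged over the sexes. The 13 comparisons were 24 and 48 h against 0 h and 48 h against 24 h in each age, adult against infant at 0 h, the age difference of the 24 h and 48 h changes, male against female in each age, and the sex difference of the time changes in each age (a moderated F-test on both times). P values were adjusted by Benjamini and Hochberg over all genes of a comparison, and genes with an adjusted p under 0.05 passed. Levels are log2 after scaling; folds are ratios of means on that scale.

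Fixed gene lists, 33 in number, were tested with camera (limma) at a preset inter-gene correlation of 0.01 in 9 comparisons, and again with the correlation estimated from the data. They were p53 targets, DNA repair, G1 and S, G2 and M, erythroid, granulocyte, B cell, T and NK cell, macrophage and Kupffer cell, megakaryocyte and platelet, endothelial, stellate cell and fibroblast, cholangiocyte, interferon-stimulated, acute phase, cytokine and chemokine, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation with PPARA targets, gluconeogenesis, bile acid, xenobiotic metabolism, NRF2 targets, unfolded protein response, heat shock, circadian clock, fetal liver, imprinted network, hepatocyte maturation, male-biased, female-biased, pancreatic acinar, and muscle and adipose lists. Lists were written from general knowledge, and at least 5 tested members were required. Adjustment was over the 33 lists of a comparison. Members were counted as passing over all genes, and again with p values adjusted over the list alone.

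The choices above, the settings to compare and the rule for naming genes were set before the data were examined. Named genes were those set beforehand: Cdkn1a, Mdm2, Ccng1, Bax, Phlda3, Eda2r and Trp53inp1 over time, Afp, H19 and Igf2 between ages, Xist and Ddx3y between sexes. To these came up to 8 passing genes with the largest rise and 8 with the largest fall in the time and age comparisons, whose arrays did not overlap within either sex and whose probe was well above background on all 4 arrays of the higher group. For the age differences and the sex comparisons up to 6 each way were taken, and up to 4 members of each list. A selection of these is given, and some are not reported here. Where a gene lay below background on all arrays of the lower group its fold is a lower bound, taken against the background floor, the dimmest spot marked well above background on each array.

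The pipeline was first run on simulated arrays with the means and spread of the real genes, 200 of 23115 genes changed by a known fold. At 1.5, 2 and 4-fold it recovered 55.2%, 85.1% and 95.5% in infants at 24 h against 0 h, 44.8%, 71.6% and 92.4% at 48 h, 53.7%, 85.1% and 98.5% in adults at 24 h, and 52.2%, 70.1% and 93.9% at 48 h. For 48 against 24 h it recovered 55.2%, 70.1% and 93.9% in infants and 43.3%, 73.1% and 92.4% in adults, and for age at 0 h 52.2%, 77.6% and 93.9%. For the age differences it recovered 20.9%, 52.2% and 81.8% at 24 h and 22.4%, 53.7% and 83.3% at 48 h. For sex it recovered 62.7%, 77.6% and 98.5% in adults and 61.2%, 79.1% and 95.5% in infants. For the sex difference of the time changes it recovered 0%, 22.4% and 60.6% in adults and 1.49%, 26.9% and 51.5% in infants. A simulated list of 25 genes shifted 2-fold passed in camera, and 0 unshifted lists passed. False calls made up between 1.85% and 9.14% of the calls. Genes were simulated independently and without slide effects, so neither the list result nor this share covers correlated genes or slides.

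The settings compared were quantile normalization, normexp background correction (offset 50), median scaling, no filter and a stricter filter on dim probes, the mean of a gene's probes, the deposited values, sex left out, the replicate label as a block, arrays of 1 age only, slide as a fixed term (with sex additive within each age, as slide follows sex and time), an intensity trend with robust priors, array weights, and each array left out in turn. Normexp was planned on the spot mean; the mean signal column was absent from the files, so the spot median was used. Alternatives added later were an additive sex term within each age, slide as a random block with that term (estimated correlation 0.265), and the adult 0 h males left out. Within-slide values used the cells of 1 slide. These cells also enter the comparison that chose the passing genes. The share that kept their direction is thus largely built in. Where only some arrays of the lower group measured a gene, its fold is the fitted one unless the floor is named, and then the unmeasured arrays were raised to it. Adult changes within each sex and their difference, sex differences at each time, lists at 48 h against 24 h, divisions with each sex divided evenly, and lists limited to members well above background on all adult 0 h arrays were added after the results were seen. Shared 0 h groups were weighed against 20 simulations without effects, against independent lists, and with the 0 h arrays divided between comparisons. Counts were compared with all 35 divisions of the 8 arrays of a comparison into 4 and 4, or with 100 drawn regroupings, the real one included. A value moved when its count differed by over 1.5-fold.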

Results

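Liver RNA of B6C3F1 mice was read on 24 single-colour arrays, 1 per mouse. Mice were 1 week old (infant) or 7 weeks old (adult), and livers were taken 0, 24 or 48 h after 4 Gy of gamma rays. Each of the 6 groups of age and time held 2 males and 2 females, which the labels name as separate animals (n = 4). The sample labels place the 0 h mice after exposure, while the protocol text also mentions sham-irradiated mice, so 0 h is used only as the name of the reference group. The brightness of the arrays, read as the 75th percentile of the probes, ran from 175 to 389 intensity units, and between 41.5% and 52% of the probes lay well above background. Replicates of the same age, time and sex correlated at 0.986 to 0.993. Signal from 23115 genes entered the tests. The arrays lay on 3 slides, and no slide held all groups.

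Infant and adult liver at 0 h differed in many genes. Mup1 was at least 12600-fold and Mup5 at least 8480-fold higher in adults (n = 4 per age). These genes encode urinary proteins made by mature hepatocytes. Here "at least" marks genes that lay below the well-above-background mark on all arrays of the lower group, whose levels were raised to the background floor before the fold was taken. Cyp7b1 was 157-fold, Scd1 194-fold, Thrsp 284-fold and Hamp 191-fold higher in adults. Orm1 was 1470-fold higher and Mup20 4870-fold higher, with Orm1 measured on 2 and Mup20 on 3 of the 4 infant arrays. Infant liver carried the fetal and imprinted transcripts: Afp was 928-fold higher (log2 -9.86, SE 0.30, adjusted p 3.2e-12 with limma), Igf2 at least 649-fold, Dlk1 at least 84.8-fold and Cdkn1c 41.1-fold. H19 was 7210-fold higher in infants against the floor, with 1 of 4 adult arrays measuring it.

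Infant liver at 0 h also carried transcripts of blood formation, which takes place in the liver before it moves to bone marrow. Mpo was at least 310-fold, Ltf at least 391-fold, Stfa1 at least 1640-fold and Camp 152-fold higher in infants than in adults. Gata1 was at least 40.7-fold, Pf4 28.6-fold, Gp1ba at least 14.5-fold, Vpreb1 15.5-fold and Rag1 at least 3.1-fold higher. Dividing-cell genes stood out in the same direction, with Birc5 16.9-fold, Rrm2 11.8-fold and Bub1 at least 9.1-fold higher, as did the matrix genes Col1a2 (8.34-fold) and Col3a1 (7.92-fold).

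With limma, 16357 of 23115 genes (70.8%) passed between adult and infant liver at 0 h, 10816 higher in adults and 5541 lower; 4163 were at least 2-fold higher and 2929 at least 2-fold lower. All 28 G2 and M genes were lower in adults (median log2 -3.80, camera adjusted p 1.41e-18, adjusted p = 0.0497 with an estimated correlation), as were all 16 fetal liver genes (median log2 -6.67, adjusted p 9.63e-14, with an estimated correlation 0.00128). All 15 megakaryocyte and platelet markers were lower (adjusted p 5.78e-11, with an estimated correlation 0.0497). Of 22 granulocyte markers 19 were lower and 1 higher, of 19 B cell markers 15 were lower and 1 higher, and of 26 erythroid markers 23 were lower and 1 higher. For granulocytes the camera adjusted p was 2.95e-12 (0.0497 with an estimated correlation) and for B cells 3.61e-08 (0.0400). The erythroid call was lost, at 1.40e-11 but adjusted p = 0.107 with an estimated correlation.

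Of 15 genes of the imprinted gene network 12 were lower and 2 higher in adults (camera adjusted p 3.90e-08, 0.0181 with an estimated correlation). All 25 male-biased adult liver genes were higher (median log2 4.53, adjusted p 5.71e-12, 0.0124 with an estimated correlation). Among 27 female-biased genes 10 were higher and 15 lower. Of 20 stellate cell and fibroblast markers 16 were lower and none higher (adjusted p 1.07e-08, 0.0497 with an estimated correlation). Of 29 hepatocyte maturation genes 26 were higher, none lower (adjusted p 4.62e-08, but adjusted p = 0.0801 with an estimated correlation). Macrophage and Kupffer cell markers were lower for 16 of 20 and endothelial markers for 11 of 17, with 1 endothelial gene higher. Of 31 DNA repair genes 7 were higher and 18 lower (adjusted p 7.22e-05, but adjusted p = 0.0801 with an estimated correlation). The median of all genes stood 0.31 log2 above 0 in adults, and after quantile normalization 53.3% of the passing genes were higher, against 66.1% without it and 55.5% after median scaling. No slide held 0 h arrays of both ages, and 10071 genes passed with slide as a fixed term.

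Infant liver 24 h after exposure showed a p53 response and a loss of blood cell transcripts. Phlda3, a p53 target, rose 7.31-fold (mean log2 level 0.53 with SD 0.13 at 0 h, 3.40 with SD 0.09 at 24 h, n = 4, adjusted p 6.9e-05 with limma). Other p53 targets rose too: Ccng1 3.88-fold (SE 0.12 log2), Zmat3 3.41-fold (SE 0.08 log2), Aen 2.95-fold, Bax 2.32-fold, Cdkn1a 2.25-fold (a call lost in 10 settings) and Mdm2 1.33-fold. The log2 change of Trp53inp1 was 0.23 (adjusted p 0.36). Eda2r did not pass the brightness filter. Of 36 p53 target genes 20 were higher, 1 lower and 15 did not pass; adjusted over the list alone, 21 were higher and 2 lower. Their median log2 change was 0.53 (camera adjusted p 1.66e-07, but adjusted p = 0.107 with an estimated correlation).

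**Figure D1:**
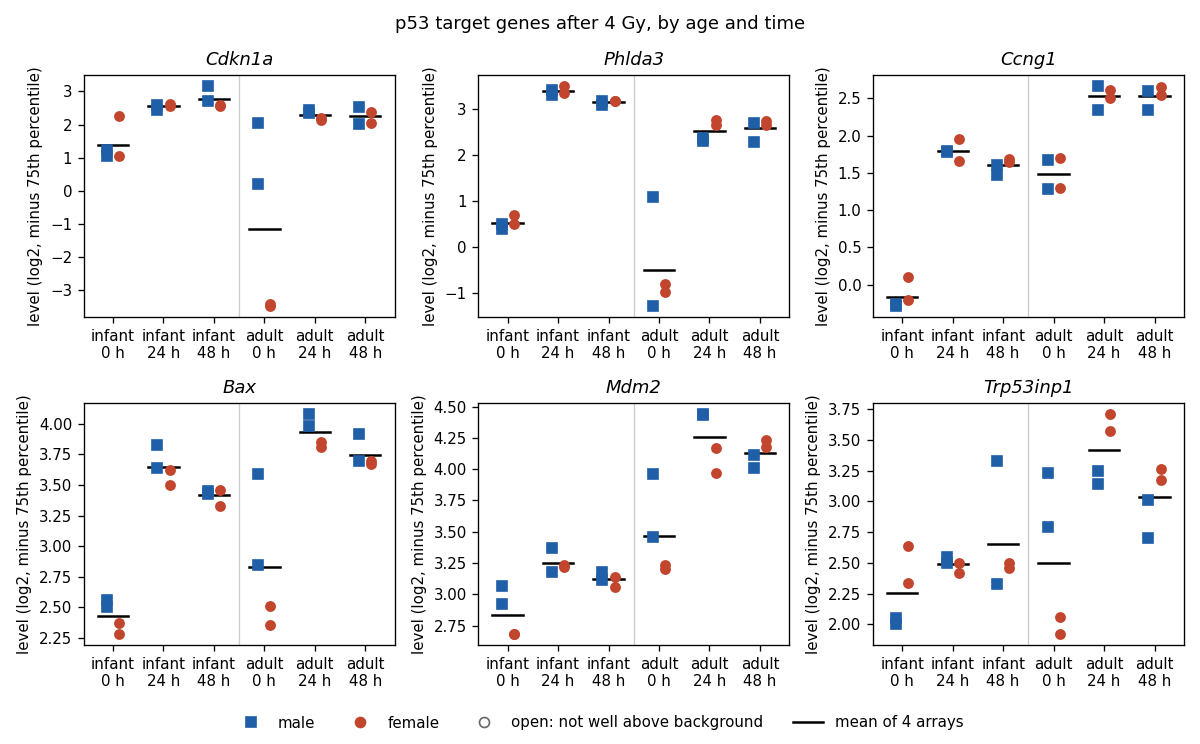
Levels of 6 p53 target genes on each of the 24 arrays (log2 minus the 75th percentile of the array), by age and time, with the mean of the 4 arrays of each group as a bar. Squares are males and circles are females.

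Red-cell precursor genes fell at 24 h in infants. Rhd, a blood group gene, fell 49.7-fold (3 of 4 arrays measured it at 24 h) and Kel 40.4-fold (3 of 4), or 37.2-fold and 27.2-fold with the other array raised to the background floor. Cldn13 was measured on 1 of 4 arrays at 24 h and fell 15.4-fold against that floor. Add2 fell at least 16.9-fold, Icam4 at least 13.6-fold and the erythroid master regulator Gata1 7.55-fold. Normexp correction, which adds an offset, shrank the falls of dim genes, to -3.99 log2 for Rhd and -2.2 log2 for Add2. Of 26 erythroid cell markers 21 were lower and 1 higher (adjusted over the list alone, 22 and 1), with a median log2 change of -2.70 (camera adjusted p 1.56e-25, and 0.0446 with an estimated correlation). Early B cell genes fell too: Vpreb3 45.1-fold (SE 0.21 log2), Pou2af1 26.1-fold (3 of 4 arrays at 24 h), Vpreb1 16.6-fold, Igll1 at least 11.4-fold and Rag1 at least 3.65-fold. Of 19 B cell markers 14 were lower and none higher (16 adjusted over the list alone), with median log2 -2.43 (adjusted p 2.90e-23, and 0.00165 with an estimated correlation).

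T and NK cell markers were lower for 13 of 21 in infants at 24 h, none higher (14 adjusted over the list alone), with Cd2 down 5.96-fold (camera adjusted p 6.78e-12, and 0.0353 with an estimated correlation). Among myeloid genes Mpo fell 8.59-fold, Ctsg 7.40-fold, Elane 3.92-fold and Camp 2.90-fold. Of 22 granulocyte markers 9 were lower and none higher (12 adjusted over the list alone, camera adjusted p 2.55e-11, but adjusted p = 0.107 with an estimated correlation). Megakaryocyte and platelet markers were lower for 6 of 15 (6 adjusted over the list alone; 2.03e-05, but adjusted p = 0.223 with an estimated correlation). Of 20 macrophage and Kupffer cell markers 6 were higher and 1 lower (7 and 1 adjusted over the list alone), and the list did not pass (adjusted p 0.0736).

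Interferon-stimulated genes were modestly higher in infants at 24 h, among them Igtp (1.95-fold), Bst2 (1.74-fold) and Ifih1 (log2 0.68). Of 28 tested, 17 were higher and 1 lower (24 and 1 adjusted over the list alone; camera adjusted p 6.37e-07, but adjusted p = 0.336 with an estimated correlation). Cell division changed little: of 28 G2 and M genes 4 were lower and none higher (3 adjusted over the list alone), with Kif23 down 2.30-fold and Mki67 down 2.04-fold. The median log2 change of these genes was -0.30 (adjusted p 2.36e-05, but adjusted p = 0.336 with an estimated correlation). The liver peptide hormone gene Hamp rose 14-fold (SE 0.28 log2, adjusted p 1.4e-06). Cps1 of the urea cycle rose 2.86-fold and Scd1 of lipid synthesis 3.38-fold.

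With limma, 4672 genes (20.2%) passed at 24 h in infants, 3175 higher and 1497 lower; 242 were at least 2-fold higher and 413 at least 2-fold lower. With slide as a fixed term 2408 passed. Within slide 1, among males, 3823 passed, where 99.9% of the 4672 kept their direction. These males are part of the average that chose the 4672, so a shared direction is largely built in. Of the 31 passing genes named for this time 30 passed within slide 1 too. Of the passing genes 68% were higher, against 56.5% after quantile normalization and 53.4% after median scaling, where 1495 genes passed. Without the infant 24 h female1 array 2757 genes passed.

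At 48 h the loss of blood cell transcripts in infants persisted. Slc4a1, the red-cell anion exchanger, fell 293-fold (SE 0.41 log2, adjusted p 1.2e-08; 2 of 4 arrays measured it at 48 h). Rhd fell at least 85.8-fold, Kel at least 46.1-fold, Ctse at least 28.1-fold, Trim10 at least 22.6-fold and Gata1 15.4-fold. Of 26 erythroid markers 23 were lower and 1 higher (23 and 1 adjusted over the list alone), with median log2 -3.64 (camera adjusted p 1.03e-26, and 0.0384 with an estimated correlation). Granulocyte genes fell too: Mpo 43.4-fold, Ctsg 30.2-fold, Camp 16-fold and Elane 5.63-fold. Of 22 granulocyte markers 19 were lower and none higher (20 adjusted over the list alone), with median log2 -2.90 (adjusted p 5.05e-21, and 0.0357 with an estimated correlation). Against 24 h 15 of 22 were lower (1.24e-29, and 0.0184 with an estimated correlation).

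B cell markers stayed low in infants at 48 h, with Vpreb3 down 28-fold, Vpreb1 18.4-fold and Ms4a1 12.1-fold (2 of 4 arrays at 48 h). Of 19, 15 were lower and none higher (15 adjusted over the list alone; camera adjusted p 1.42e-18, and 0.00489 with an estimated correlation). Platelet-line genes were lower as well, with Nfe2 down 10.7-fold, Gp1ba 3.70-fold and Pf4 2.35-fold. Of 15 megakaryocyte and platelet markers 14 were lower (15 adjusted over the list alone; 2.07e-10, but adjusted p = 0.0523 with an estimated correlation). Among 21 T and NK cell markers 15 were lower and 1 higher (15 and 1 adjusted over the list alone; 5.42e-08, but adjusted p = 0.0523 with an estimated correlation). Of 20 stellate cell and fibroblast markers 11 were higher, none lower (11 adjusted over the list alone; 0.0160, but adjusted p = 0.437 with an estimated correlation).

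**Figure D2:**
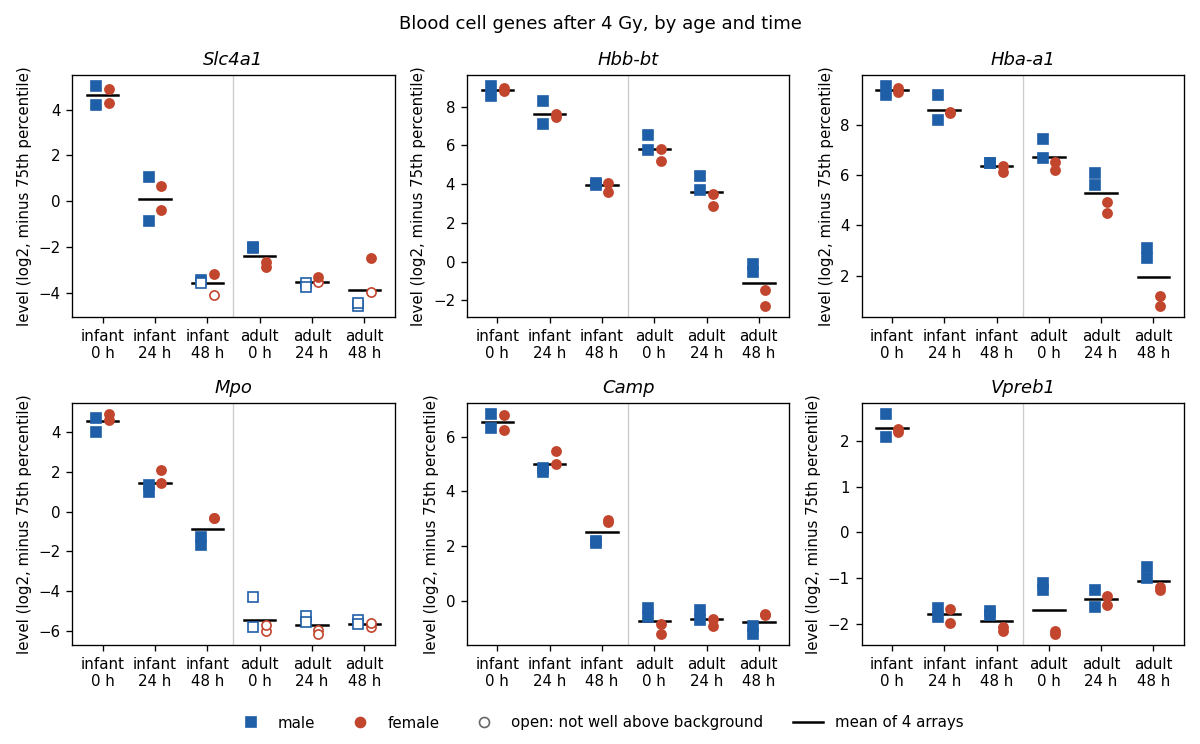
Levels of the red-cell genes Slc4a1, Hbb-bt and Hba-a1, the granulocyte genes Mpo and Camp and the early B cell gene Vpreb1 on each of the 24 arrays (log2 minus the 75th percentile of the array), with group means of 4 arrays as bars. Open symbols are arrays on which the probe was not well above background.

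Hepcidin genes rose in infants by 48 h, Hamp2 142-fold (SE 0.46 log2, adjusted p 1.5e-07) and Hamp 69.9-fold, as did Cyp2c38 (7.67-fold). The p53 response persisted, with Phlda3 6.18-fold, Zmat3 3.44-fold, Ccng1 3.40-fold, Cdkn1a 2.59-fold, Bax 1.99-fold and Mdm2 1.22-fold up, the Mdm2 call lost in 14 settings. The log2 change of Trp53inp1 was 0.40 (adjusted p 0.079). Of 36 p53 target genes 23 were higher and 4 lower (24 and 5 adjusted over the list alone), with median log2 0.73 (camera adjusted p 0.000155, but adjusted p = 0.221 with an estimated correlation). Interferon-stimulated genes were higher for 16 of 28 and lower for 1, Rsad2, which fell 3.09-fold (21 and 1 adjusted over the list alone; 0.00320, but adjusted p = 0.626 with an estimated correlation). Mitotic genes no longer leaned one way: of 28 G2 and M genes 3 were higher, among them Birc5 (log2 0.56), and 2 lower (3 and 2 adjusted over the list alone). Their median log2 was 0.17 and mean 0.11, while the camera test pointed down (adjusted p 0.887).

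With limma, 8094 genes (35%) passed at 48 h in infants, 5511 higher and 2583 lower; 319 were at least 2-fold higher and 749 at least 2-fold lower. A fixed slide term left 7498. Within slide 1, among males, 7116 passed and 99.9% of the 8094 kept their direction; within slide 2, among females, 2596 passed and 98.2% kept it. Of the 34 passing genes named for this time 33 and 30 passed there too. Of the passing genes 68.1% were higher, against 56.8% after quantile normalization; after median scaling 4376 genes passed. Leaving out sex gave 4615.

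From 24 to 48 h infant liver changed in few genes. Hbb-bt, a beta globin, fell 13-fold (SE 0.30 log2, adjusted p 1.8e-05 with limma) and Slc4a1 12.8-fold (2 of 4 arrays at 48 h). Granulocyte genes fell as well: Ltf 5.60-fold, Camp 5.52-fold and Mpo 5.05-fold. Hamp2 rose 22.4-fold, Chac1 5.25-fold and Hamp 5-fold, while the mitotic gene Birc5 rose 1.69-fold, a call lost in 10 settings. None of the p53 targets Cdkn1a, Mdm2, Ccng1, Bax, Phlda3 and Trp53inp1 passed. In all 456 genes passed (1.97%), 272 higher and 184 lower; 105 passed with slide as a fixed term and 91 within slide 1, among males, where 100% of the 456 kept their direction. After median scaling 163 passed, 36.2% of them higher against 59.6%, and without the infant 48 h female1 array 178 passed.

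Adult liver 24 h after exposure showed an interferon response and a loss of mitotic transcripts beside the p53 response, and acute phase genes passed in females. Cdkn1a, the cell cycle inhibitor under p53, rose 10.9-fold (mean log2 level -1.16 with SD 2.75 at 0 h, 2.28 with SD 0.13 at 24 h, n = 4, adjusted p 8.7e-05). Its 0 h level split by sex, at -3.49 and -3.42 in females and 2.05 and 0.21 in males. Females rose by 5.63 log2 (adjusted p 2.2e-05) and males by 1.26 (adjusted p 0.081). Phlda3 rose 8.13-fold, Ddias 3.78-fold, Aen 2.33-fold, Bax 2.14-fold, Ccng1 2.06-fold and Mdm2 1.73-fold. Trp53inp1 rose 1.89-fold on average, by 1.65 log2 in females and 0.18 (limma adjusted p 0.65) in males. Of 36 p53 target genes 21 were higher and none lower (24 and 1 adjusted over the list alone), with median log2 0.49 (camera adjusted p 2.32e-12, but adjusted p = 0.0859 with an estimated correlation).

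Interferon-stimulated genes rose almost throughout in adults at 24 h. Isg15 rose 5.06-fold (SE 0.24 log2, adjusted p 0.00015), Ifit1 4.88-fold, Irf7 3.69-fold, Cmpk2 3.43-fold and Oas3 3.28-fold against the floor (1 of 4 arrays measured Oas3 at 0 h). Of 28 tested, 27 were higher and none lower (28 adjusted over the list alone), with median log2 1.5 (camera adjusted p 2.24e-28, but adjusted p = 0.103 with an estimated correlation). Serum amyloid and other acute phase genes rose beside them on average: Saa1 9.83-fold (SE 0.39 log2), Saa2 7.10-fold and Serpina3n by 1.52 log2. Of 25 acute phase genes 9 were higher and none lower (17 adjusted over the list alone; 2.71e-08, but adjusted p = 0.513 with an estimated correlation). In females 13 were higher and in males none, and the change itself was lower in males for 4 of 25 (0.000362, but adjusted p = 0.908 with an estimated correlation). Saa1 changed by 5.37 log2 in females and 1.23 (adjusted p 0.16) in males (difference -4.14, adjusted p 0.0057), who stood higher by 4.26 log2 at 0 h. The 16 inflammatory cytokines and chemokines gave 1 higher and none lower (adjusted p 0.403). Of 20 macrophage and Kupffer cell markers 9 were higher, among them Fcgr1 (2.34-fold) and Cd5l (1.72-fold), and none lower; adjusted over the list alone, 14 were higher and 2 lower (2.47e-05, but adjusted p = 0.513 with an estimated correlation).

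Mitotic genes fell in adult liver at 24 h. Cdc20 fell 5.07-fold, Plk1 4.44-fold (1 of 4 arrays measured it at 24 h), Mki67 4.12-fold (3 of 4), Birc5 2.84-fold, Prc1 at least 3.55-fold and Ccna2 at least 3.36-fold (log2 -3.27, and -0.91 after normexp correction). Of 28 G2 and M genes 23 were lower and none higher (25 adjusted over the list alone), with median log2 -1.27 (camera adjusted p 2.42e-23, but adjusted p = 0.103 with an estimated correlation). In females 24 of 28 were lower (median log2 -1.87) and in males 12 (median log2 -0.81), and the change itself was higher in males for 8 of 28 (1.53e-06, but adjusted p = 0.908 with an estimated correlation). At 0 h 19 of 28 were lower in males than in females (1.61e-09, but adjusted p = 0.399 with an estimated correlation). Genes of G1 and S followed, with Rrm2 down 2.47-fold: of 25, 11 were lower and 1 higher (13 and 1 adjusted over the list alone; 3.78e-06, but adjusted p = 0.469 with an estimated correlation). Of 31 DNA repair genes 5 were lower and none higher (7 and 1 adjusted over the list alone; adjusted p 0.176).

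Globin transcripts were already lower in adults at 24 h, with Hbb-bt down 4.62-fold and Hba-a1 2.70-fold. Of 26 erythroid markers 4 were lower and none higher (4 adjusted over the list alone). The median log2 was 0.03 and the mean -0.25, with an adjusted p of 0.216. Only 14 of the 26 were well above background on all adult 0 h arrays, with a median log2 of -0.36 (camera adjusted p 0.0237, but adjusted p = 0.586 with an estimated correlation). Of 19 B cell markers 6 were lower, none higher (6 adjusted over the list alone, camera adjusted p 0.0102, but adjusted p = 0.513 with an estimated correlation). In females 6 were lower and 2 higher, and in males 1 was lower and none higher. The change itself was higher in males for 4 of 19 and lower for 2 (camera adjusted p 0.156). At 0 h 7 of 19 were lower and 2 higher in males than in females (camera adjusted p 0.0535). Afp rose 2.43-fold (adjusted p 0.013) and H19 2.83-fold against the floor (adjusted p 0.033, a call lost in 15 settings; 3 of 4 arrays at 24 h and 1 of 4 at 0 h), with male1 far above the other adults, for which a trace of infant RNA was not excluded.

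With limma, 3220 genes (13.9%) passed at 24 h in adults, 1719 higher and 1501 lower; 123 were at least 2-fold higher and 193 at least 2-fold lower. Adding slide as a fixed term gave 3122, 40.3% of them higher against 53.4%. Within slide 3, among females, 3404 passed and 96.4% of the 3220 kept their direction; of the 29 passing genes named for this time 27 passed there too. After median scaling 674 passed, with sex left out 718, and without the adult 24 h female1 array 1971. Each adult change from 0 h rests on 0 h males and females that differed in clock genes.

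Globins dominated adult liver at 48 h. Hbb-bt fell 122-fold (SE 0.30 log2, adjusted p 3.5e-08), Hbb-b2 46.2-fold, Hbb-b1 41.6-fold (3 of 4 arrays at 48 h), Hba-a1 27.6-fold and Hba-a2 21.2-fold. Of 26 erythroid markers 6 were lower, none higher (6 adjusted over the list alone), with median log2 -0.10 (camera adjusted p 0.0103, but adjusted p = 0.765 with an estimated correlation). Among the 14 well above background on all adult 0 h arrays the median log2 was -0.44 (1.04e-05, but adjusted p = 0.329 with an estimated correlation). Cd79b of B cells fell 3.72-fold (2 of 4 arrays at 48 h), with a change of -2.82 log2 in females and -0.97 in males. Of 19 B cell markers 6 were lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p 0.0103, but adjusted p = 0.538 with an estimated correlation). In females 5 were lower and 1 higher, and in males 3 were lower and none higher.

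The p53 response held in adults at 48 h, with Cdkn1a up 10.6-fold (5.68 log2 in females and 1.14, adjusted p 0.11, in males), Phlda3 8.56-fold, Ddias 3.75-fold, Aen 2.20-fold, Ccng1 2.05-fold, Bax 1.89-fold and Mdm2 1.59-fold. The log2 change of Trp53inp1 was 0.53 (adjusted p 0.052). Of 36 p53 target genes 15 were higher and 2 lower (21 and 2 adjusted over the list alone; camera adjusted p 3.24e-10, but adjusted p = 0.113 with an estimated correlation). G2 and M genes stayed low on average: Ccnb1 fell 3.12-fold against the floor (2 of 4 arrays at 48 h), Cenpe at least 3.93-fold, Prc1 at least 3.64-fold and Birc5 2.72-fold. Of 28, 23 were lower and none higher (24 adjusted over the list alone), with median log2 -1.22 (2.33e-22, but adjusted p = 0.113 with an estimated correlation). In females 24 of 28 were lower and in males 2, and the change itself was higher in males for 15 of 28 (9.73e-12, but adjusted p = 0.596 with an estimated correlation). Birc5 changed by -2.59 log2 in females and -0.29 (adjusted p 0.36) in males, a difference of 2.3 (adjusted p 0.00067). Gadd45g rose 5.47-fold (4.13 log2 in females and 0.77, adjusted p 0.55, in males) and Id3 3.55-fold.

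The interferon response had faded in adults by 48 h. Of 28 interferon-stimulated genes 7 were higher than at 0 h and none lower (11 adjusted over the list alone), among them Irf7 (log2 0.95), with median log2 0.42 (camera adjusted p 8.22e-06, but adjusted p = 0.71 with an estimated correlation). Acute phase genes remained up on average, with Saa1 6.19-fold (4.63 log2 in females and 0.63, adjusted p 0.48, in males): of 25, 6 were higher and none lower (8 adjusted over the list alone; 1.02e-05, but adjusted p = 0.71 with an estimated correlation). Of 17 endothelial markers 1, Stab2, was lower (log2 -0.40, a call lost in 24 settings) and none higher, with none passing when adjusted over the list alone (0.00425, but adjusted p = 0.765 with an estimated correlation).

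With limma, 2722 genes (11.8%) passed at 48 h in adults, 1267 higher and 1455 lower; 56 were at least 2-fold higher and 389 at least 2-fold lower. With slide as a fixed term 1910 passed, 32.8% of them higher. Within slide 3, among females, 1858 passed and 95.2% of the 2722 kept their direction; of the 23 passing genes named for this time 22 passed there too. Of the passing genes 46.5% were higher, against 77.5% after median scaling (1589 genes, the median of all genes at 0.20 log2) and 57.3% with the deposited values (2880 genes). With sex left out 189 passed, and without the adult 48 h female1 array 1468.

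**Figure D3:**
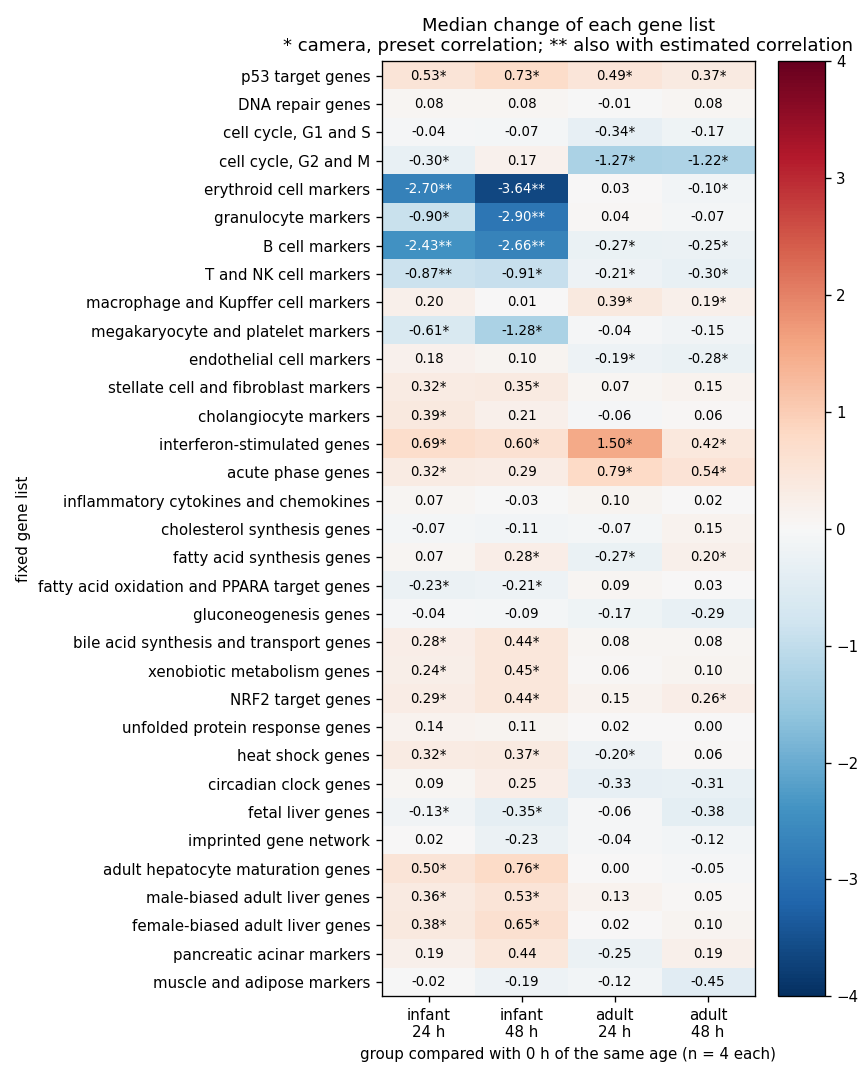
Median log2 change of the tested members of each of the 33 fixed gene lists at 24 and 48 h against 0 h of the same age (n = 4 per group). The interferon list reached 1.5 in adults at 24 h and the erythroid list -3.64 in infants at 48 h.

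Between 24 and 48 h adult liver lost globin and interferon transcripts. Hbb-bt fell 26.5-fold (adjusted p 6e-06 with limma), Hbb-b2 13.2-fold and Hba-a1 10.2-fold. Ifit1 fell 3.62-fold, Ifi44 3.55-fold and Isg15 3.27-fold. Fasn rose 2.77-fold and Ccnd1 2.29-fold (lost in 10 settings), and none of the p53 targets Cdkn1a, Mdm2, Ccng1, Bax, Phlda3 and Trp53inp1 passed. In all 381 genes passed (1.65%), 145 higher and 236 lower. Within slide 2, among males, 85 passed and 96.1% of the 381 kept their direction; within slide 3, among females, 851 passed and 99.7% kept it; with slide as a fixed term 221 passed. Of the 381, 38.1% were higher, against 49% after quantile normalization and 50.6% after median scaling (164 genes, the median of all genes at 0.15 log2); with only adult arrays in the fit 6 passed, and without the adult 24 h female2 array 110.

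Changes at 24 and 48 h shared their 0 h group. In infants the log2 changes at the 24 h and 48 h times correlated at 0.86 across genes, in adults at 0.60; a shared 0 h group alone gave 0.50 in each age over 20 simulations. With the 0 h arrays divided between the comparisons the values were 0.71 and 0.44. In infants 2770 genes were higher at both times, 1265 lower at both and 3 opposite, where independent lists would share 757 and 167. With divided 0 h arrays these were 1436 and 726, with 14 opposite, against 322 and 74.3. In adults 698 were higher at both, 659 lower at both and 1 opposite, against 94.2 and 94.5. With divided 0 h arrays these were 246 and 257, with 9 opposite, against 28.8 and 21.4.

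The 24 h change of single genes differed between infants and adults. Growth of the infants over that time enters each age difference, since unirradiated infants of the later ages were not analysed here. Camp fell in infants (log2 -1.53) and lay at 0.07 in adults (difference 1.61, SE 0.23, adjusted p 0.00078 with limma). Cdc20 fell in adults alone (-2.34 against 0.29, difference -2.63). Isg15 rose more in adults (2.34 against 0.55, difference 1.79, adjusted p 0.0048), and Hamp (difference -2.77), Cps1 (-1.44) and the p53 target Zmat3 (-1.35) rose more in infants.

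Of 19 B cell markers 13 had a higher change in adults and none a lower one (13 adjusted over the list alone; camera adjusted p 2.80e-13, and 0.0198 with an estimated correlation). For 26 erythroid markers the split was 17 and 0 (20 and 2 adjusted over the list alone; 2.18e-14, but adjusted p = 0.241 with an estimated correlation). Interferon-stimulated genes were higher in adults for 9 of 28 and lower for none (14 adjusted over the list alone; 1.67e-08, but adjusted p = 0.428 with an estimated correlation). G2 and M genes were lower for 12 of 28 (18 adjusted over the list alone, camera adjusted p 4.98e-07, but adjusted p = 0.428 with an estimated correlation). The adult fall itself passed for 24 of 28 in females and 12 in males. The 36 p53 target genes gave 2 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p 0.98), with median, mean and test differing in sign. Genes at the background floor can show no adult fall, and for Rhd, Rag1 and Mpo no age difference is therefore given. Among those well above background on all adult 0 h arrays, 5 of 10 B cell markers were higher (6.27e-06, and 0.00691 with an estimated correlation) and 6 of 14 erythroid markers (0.00105, but adjusted p = 0.375 with an estimated correlation), none lower. In all 3346 genes passed (14.5%), 1340 with a higher and 2006 with a lower change in adults. A fixed slide term left 2740. Within slides, with infant males on slide 1 and adult females on slide 3, 3843 passed and 99% of the 3346 kept their direction. Of the 3346, 40% had a higher change in adults, against 55.5% after median scaling (825 genes); without the infant 24 h female1 array 2187 passed.

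At 48 h the age difference, which again includes growth of the infants, was large for the hepcidin gene Hamp2. It rose in infants alone (7.15 against 0.41, difference -6.74, SE 0.65, adjusted p 2.2e-05). Camp fell in infants (-4 log2) and lay at -0.05 in adults (difference 3.94). Birc5 fell in adults on average and rose in infants (-1.44 against 0.56, difference -2, adjusted p 2.8e-05). The adult change was -2.59 log2 in females and -0.29 in males (limma adjusted p 0.36). The p53 targets Zmat3 (difference -1.31) and Ccng1 (-0.73) rose more in infants, but of 36 p53 target genes 3 had a higher and 7 a lower change in adults (4 and 7 adjusted over the list alone) and the list did not pass (adjusted p 0.932).

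Of 22 granulocyte markers 16 had a higher change in adults and none a lower one (18 adjusted over the list alone; camera adjusted p 1.79e-20, and 0.0373 with an estimated correlation). Of 19 B cell markers 11 were higher and 1 lower (13 and 1 adjusted over the list alone; 4.42e-14, and 0.0164 with an estimated correlation). Erythroid markers gave 19 higher and 4 lower of 26 (19 and 4 adjusted over the list alone; 2.21e-15, but adjusted p = 0.154 with an estimated correlation). The lower ones were globins, which fell more in adults: Hbb-bt (-6.93 against -4.94, difference -2, adjusted p 0.0056), Hba-a1 (-4.79 against -3.01), Hba-a2 (-4.41 against -1.76) and Hbb-b1 (-5.38 against -3.66). G2 and M genes gave 20 lower of 28 (23 adjusted over the list alone, camera adjusted p 4.78e-11, but adjusted p = 0.217 with an estimated correlation). The adult fall itself passed for 24 of 28 in females and 2 in males. The adult floor limits these lists too. Among genes well above background on all adult 0 h arrays, granulocyte markers were higher for 5 of 9 (2.05e-07, but adjusted p = 0.0774 with an estimated correlation). On the same arrays B cell markers gave 5 higher and 1 lower of 10 (1.05e-05, and 0.00907 with an estimated correlation) and erythroid markers 7 higher and 4 lower of 14 (0.0103, but adjusted p = 0.605 with an estimated correlation). In all 4467 genes passed (19.3%), 1482 with a higher and 2985 with a lower change in adults, and the median of all genes lay at -0.13 log2. Adding slide as a fixed term gave 4554. Within slides, among females, 2169 passed and 98.2% of the 4467 kept their direction. Of the 4467, 33.2% had a higher change in adults, against 46.8% after quantile normalization and 74.8% after median scaling (1562 genes).

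Between the ages 426 genes were higher at 24 h in both, 174 lower in both and 282 opposite, where independent lists would share 236 and 97.2. At 48 h these were 603, 293 and 251, against 302 and 163. No such expectation was taken for the opposite genes, so their counts alone do not show that the ages diverged. The log2 changes of infants and adults correlated at 0.11 at 24 h and 0.23 at 48 h.

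Sex shaped adult liver strongly. Cyp2b13 was at least 724-fold, Slc22a26 at least 145-fold and Sult3a1 at least 134-fold higher in females (n = 6 per sex). Cyp4a12a was 54-fold, Elovl3 53.3-fold, C6 16.2-fold and Moxd1 at least 48.8-fold higher in males. The chromosome markers followed the labels, with Ddx3y at least 68.1-fold higher in males and Xist at least 22-fold higher in females. Cdkn1a was 3.06-fold higher in males (adjusted p 0.00035), from 4.59 log2 at 0 h, with 0.22 at 24 h (adjusted p 0.79) and 0.04 at 48 h (adjusted p 0.96). All 25 male-biased genes were higher in males (camera adjusted p 1.77e-26, and 0.000313 with an estimated correlation) and 25 of 27 female-biased genes lower (6.87e-35, and 0.000313 with an estimated correlation). Of 31 xenobiotic metabolism genes 18 were lower and 4 higher in males (18 and 5 adjusted over the list alone; 9.74e-07, but adjusted p = 0.362 with an estimated correlation). With limma, 7953 genes (34.4%) passed, 4661 higher and 3292 lower in males; 371 were at least 2-fold higher and 351 at least 2-fold lower. With slide as a fixed term 4779 passed, and within slide 3 at 0 h 5236 passed, where 88.7% of the 7953 kept their direction. Of the 7953, 58.6% were higher in males, against 30.1% after median scaling (4095 genes) and 70.6% after normexp correction (11049 genes).

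Infant liver differed little between the sexes. Ddx3y was at least 90.1-fold and Eif2s3y 112-fold higher in males (1 of 6 female arrays measured Eif2s3y, and the others were raised to the background floor), and Xist at least 36.8-fold higher in females. None of 25 male-biased genes passed (camera adjusted p 0.488), and 2 of 27 female-biased genes were lower in males (3 adjusted over the list alone; 0.17). With limma, 937 genes passed (4.05%), 580 higher and 357 lower in males, with 40 at least 2-fold higher and 10 at least 2-fold lower. All infant males lay on slide 1 and the females at 0 and 48 h on slide 2, so sex followed slide in part. With slide as a fixed term 12 passed, and within slide 1 at 24 h 24 passed, where 99.1% of the 937 kept their direction. After normexp correction 9379 passed, 75.5% of them higher against 61.9%. After median scaling 156 passed, with the median of all genes at -0.13 log2, and without the infant 24 h male1 array 224.

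Males and females changed differently over time in adults. The change of Dbp, an output gene of the circadian clock, was higher in males than in females by 4.95 log2 at 24 h and by 6.62 log2 at 48 h (moderated F-test in limma, adjusted p 7.2e-05). Arntl of the clock's positive arm went the other way (-2.49 and -3.42, adjusted p 4.7e-05), and Wee1 (3.59 and 3.62) and Tef (2.09 and 2.21) followed Dbp. The mitotic gene Top2a also had the higher change in males (2.83 and 3.38, adjusted p 0.0011), though only 2 of 4 adult arrays measured it at 0 h. At 0 h, within slide 3, Dbp was lower in males by 4.75 log2 (adjusted p 2.4e-06) and Arntl higher by 2.54 log2. Of 18 circadian clock genes 3 were higher and 12 lower in males at that time (camera adjusted p 1.43e-05, and 0.00625 with an estimated correlation). In all 3071 genes passed (13.3%), with 619 when only adult arrays entered the fit, 1481 after median scaling and 1556 without the adult 0 h female2 array. Males at 24 and 48 h lay on slide 2 and the other adults on slide 3, so the test cannot be made within a slide; without the adult 0 h males the change from 24 to 48 h differed for 266 genes. In infants 0 genes passed (2360 with unadjusted p under 0.05), and from 0 to 38 when each array was left out.

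**Figure D4:**
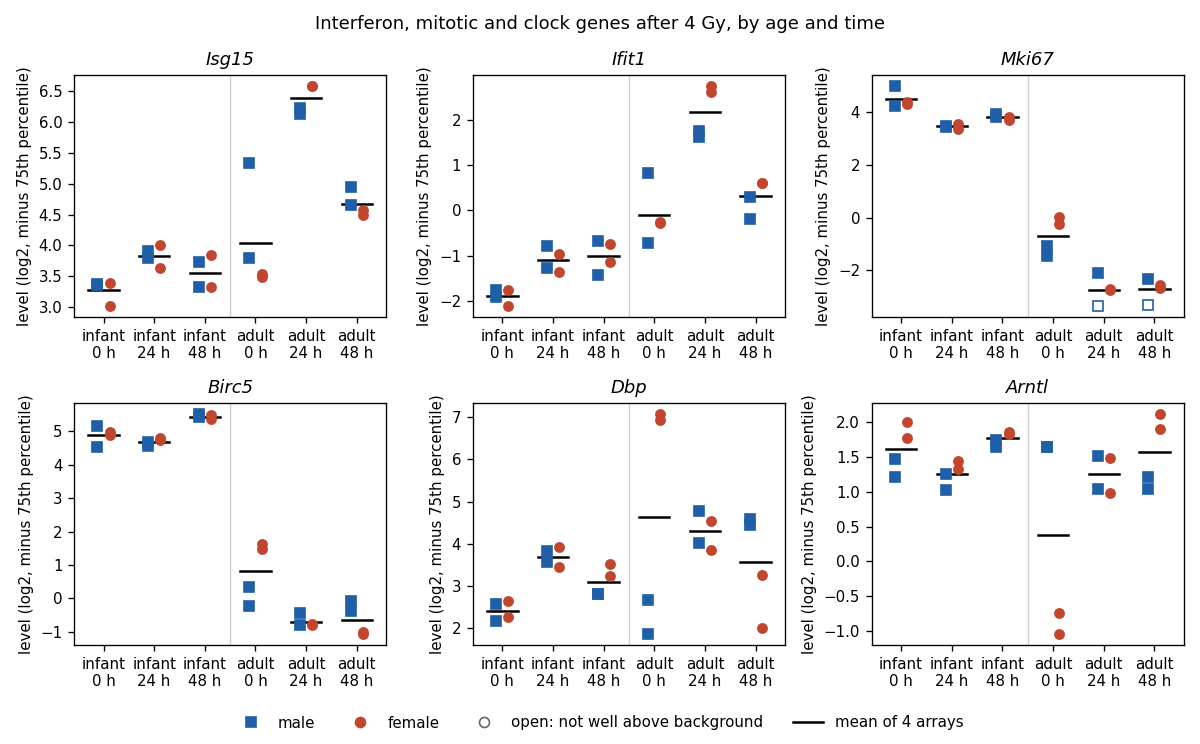
Levels of the interferon-stimulated genes Isg15 and Ifit1, the mitotic genes Mki67 and Birc5 and the clock genes Dbp and Arntl on each of the 24 arrays (log2 minus the 75th percentile of the array), with group means of 4 arrays as bars. Adult 0 h males and females lie apart for Dbp and Arntl.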

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

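The tests of clock genes and of a prior response in adult 0 h males, the tests of the infant erythroid fall, the test for infant RNA and the divisions for counts of lists were chosen after the result was seen; the slide test and the divisions for counts of genes were set before. The scaling test of the erythroid fall was restated as a percent after its values were known, and the gene set of the infant RNA test was redefined after the level of Igf2 was known.

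In 3 of 74 groups of levels tested 1 array lay far from the others by the Dixon ratio, where 5% of groups would do so by chance. Cdkn1a in infants at 0 h was higher in female2 (2.26 against a mean of 1.1, ratio 0.85). Bax in adults at 48 h was higher in male1 (3.92 against 3.69, ratio 0.86), and H19 in adults at 0 h was higher in female1 (-3.18 against -4.17, ratio 0.91). Chance alone gives such a number, and no array was left out.

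Changes from 0 h differed between infants and adults for 3346 genes at 24 h and 4467 genes at 48 h. Unirradiated infants of the later ages were not analysed here. An age difference in the response to radiation therefore cannot be told apart from growth of the infants. At 24 h the adult change exceeded the infant change by 1.61 log2 for Camp and 1.79 for Isg15. It lay lower by difference values of -2.77 for Hamp, -2.63 for Cdc20, -1.44 for Cps1 and -1.35 for Zmat3. At 48 h the differences were 3.94 for Camp, -6.74 for Hamp2, -2 for Birc5, -1.31 for Zmat3 and -0.73 for Ccng1. Rhd, Rag1 and Mpo were below background in adults, so no age difference is given for them, and the same floor limits any adult fall of the blood cell lists, with 9 of 22 granulocyte, 10 of 19 B cell and 14 of 26 erythroid markers well above background on all adult 0 h arrays.

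Adult males and females differed in their time changes for 3071 genes. Per gene the difference by 24 h and 48 h was 4.95 and 6.62 log2 for Dbp, -2.49 and -3.42 for Arntl, 3.59 and 3.62 for Wee1, 2.09 and 2.21 for Tef, and 2.83 and 3.38 for Top2a (2 of 4 adult 0 h arrays measured it). Slide remains open: the female 24 h change, made within slide 3, was the larger in 53.8% of these genes, where over 60% would argue against slide and under 40% for it. A radiation response already present in the 0 h males stays open: the lower median of their p53 targets stood 0.04 log2 above the 0 h females, against a broad one, but male1 stood at 0.49 log2 with 14 of 20 targets above both females, and 0 h males were higher for Cdkn1a (4.59 log2), Bax (0.79) and Trp53inp1 (1.02) and lower for 19 of 28 G2 and M genes. A different time of day at 0 h may explain part of it: 15 of 18 clock genes differed between the sexes at 0 h within slide 3, 0 at 24 h and 6 at 48 h, with Dbp and Arntl going opposite ways; sampling times are not given in the sources used here.

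The infant fall of blood cell transcripts at 48 h was weighed against scaling, slide and growth. Under the other scalings at least 81.2% of the tested erythroid markers stayed lower (23 of 26 with quantile, normexp and median scaling, 13 of 16 with the deposited values), which argues against scaling. The higher of the within-slide medians was -3.45 log2, which argues against slide. Growth stays open, since blood formation leaves the liver after birth and unirradiated infants of the later ages were not analysed here. By 48 h 19 of 26 erythroid markers lay at or below the adult 0 h mean. Only 14 of 26 were well above background on all adult 0 h arrays, so the count partly compares values near background.

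Afp and H19 in adult 24 h male1 may come from a trace of infant liver RNA. Of 11 other genes that the share read from H19 would at least double, 63.6% lay above all other adult arrays in male1, against at most 9.09% for another array, where over 80% would point to such RNA and under 30% against it. The share read from H19 was 0.34%, from Afp 0.94%, and the median over the 11 genes was 0.18%. Among the 11, Stfa1, Stfa2l1, Stfa3, Csta2, Cstdc4 and Cstdc5 are related genes, so the 11 are not independent. Genes that did not lie above the other arrays included Pnliprp1 (level -5.04 in male1, highest other -3.74) and Mpo (-5.24, highest other -4.28). Infant RNA as the explanation stays open.

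Other divisions of the arrays were used to ask whether chance can be excluded, counting divisions that gave as many genes as the real one. For infants the real division was the only such one, 1 of 35, at 24 h (4303 genes, highest other 88), at 48 h (7751, highest other 21) and from 24 to 48 h (520, highest other 76), as it was for age at 0 h (1 of 35; 15792, highest other 182). For adults this rule gave no answer on chance. At 24 h 2 of 35 divisions reached the real count (2261, highest other 3251), at 48 h 2 of 35 (1707, highest other 4962) and from 24 to 48 h 3 of 35 (236, highest other 6595). The highest other division parted males from females, which is the sex difference of adult liver and no chance draw, and from 24 to 48 h it also parted the slides. With each sex divided evenly 1 of 18 reached the count at 24 h (highest other 1833), 1 of 18 at 48 h (highest other 1236) and 2 of 18 from 24 to 48 h (highest other 732), too few divisions for a share under 5%. The age difference count at 24 h was reached by 1 of 100 regroupings (2084, highest other 993). At 48 h 2 of 100 reached it (3087, highest other 3450). These regroupings mixed 0 h and later arrays within each age, so a response in 1 age alone can raise the real count above them. They therefore cannot exclude chance for a difference between the ages. For sex only the real division, 1 of 100, reached the count, in adults (6513, highest other 1004) and infants (710, highest other 164). In adults the 24 and 48 h males, and in infants the 0 and 48 h females, lay on slide 2 without the other sex. Sex was thus not parted from slide, and in infants the highest other regrouping followed slide 1. For the sex difference of the time changes the regroupings gave no answer either. In adults 10 of 100 reached 3071 (highest other 9682, a regrouping that swaps the sexes at 48 h), but they turn the constant sex difference into a difference over time. In infants the real count was 0, which any regrouping reaches (100 of 100, highest other 586).

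For counts of lists passing with the preset correlation chance could not be excluded. Over the 9 comparisons 73 of 100 drawn regroupings gave at least the real 131, with 190 the highest other. The count of lists in infants was reached by 6 of 35 divisions at 24 h (20, highest other 22) and 6 of 35 at 48 h (18, highest other 20), and in adults by 9 of 35 at 24 h (12, highest other 14) and 17 of 35 at 48 h (10, highest other 14). How many lists pass with the preset correlation was thus not settled against chance and carries little weight. With an estimated correlation 20 passed.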

How the results depend on the processing

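Counts moved by over 1.5-fold under several settings; the cause was not tested. Quantile normalization gave 1811 genes for adults at 48 h against 0 h. Normexp correction gave 1755 for adults at 48 h, 9379 for sex in infants and 2 for the infant sex difference of the time changes. Median scaling gave 1495 and 4376 for infants at 24 and 48 h, 674 and 1589 for adults, 163 and 164 from 24 to 48 h in infants and adults, 825 and 1562 for the age differences, 4095 and 156 for sex in adults and infants, and 1481 and 1 for the sex difference of the time changes. Without a filter on dim probes adults gave 2076 at 24 h and 1544 at 48 h, the changes from 24 to 48 h 268 in infants and 200 in adults, sex 12025 in adults and 518 in infants, and the sex difference of the time changes 1743 and 1. With sex left out infants gave 1754 and 4615, adults 718 and 189, the 24 to 48 h changes 147 and 76, and the age differences 873 and 1392. With the replicate label as a block these were 1921 and 5058, 874 and 218, 175 and 102, and 1070 and 1714. Whether that label pairs mice was not settled. Deviations of mice with the same number from their cell mean correlated at a mean of 0.111 in males (-0.048 to 0.28). In females the mean was 0.024 (-0.204 to 0.161). Of 24 samples 17 correlated best with samples of their own sex and number, with deviations taken from the mean of both sexes. Sex alone draws samples together in such deviations, and no chance value was taken for the 17. With only the arrays of that age, sex in infants gave 423, adults 1224 and 606, adults from 24 to 48 h 6, and the adult sex difference of the time changes 619. Slide as a fixed term gave 2408 for infants at 24 h, 105 and 221 from 24 to 48 h in infants and adults, 10071 for age at 0 h, and 4779 and 12 for sex in adults and infants. Array weights gave 1603 for adults at 48 h, 1101 for infants from 24 to 48 h and 1715 for sex in infants. The deposited values moved none of the counts.

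The added alternatives were chosen after seeing the data. An additive sex term gave 2111 and 1221 for adults at 24 and 48 h, 157 from 24 to 48 h, 1954 and 2788 for the age differences and 446 for sex in infants. Slide as a random block with that term gave 3070 for infants at 24 h, 1695 and 750 for adults, 224 and 187 from 24 to 48 h, 1572 for the age difference at 24 h, and 4485 and 43 for sex in adults and infants. Without the adult 0 h males the adult sex difference of the time changes, then from 24 to 48 h alone, fell to 266 genes. With an estimated correlation 20 lists passed in place of 131.

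Leaving out each array in turn gave 2757 to 4973 genes for infants at 24 h, with moves without 24 h female1 (2757), 24 h male2 (2764), 0 h female2 (2798) and 0 h male1 (2904). At 48 h it gave 5934 to 8391 in infants. Adults at 24 h ran from 1971 to 3406 (without 24 h female1 1971, 0 h female2 2074), and at 48 h from 1468 to 2834 (without 48 h female1 1468, 0 h female2 1533, 0 h female1 1726, 48 h female2 1808). Infants from 24 to 48 h ran from 178 to 544, with moves without the 24 h arrays male1 (223), male2 (221), female1 (240) and female2 (224) and the 48 h arrays male2 (217), female1 (178) and female2 (210). Adults from 24 to 48 h ran from 110 to 627, with moves without 0 h male1 (575) or male2 (575), 24 h male1 (178), female1 (150) or female2 (110), and 48 h male1 (627), male2 (198) or female1 (135). Age at 0 h ran from 15467 to 16492, the age difference at 24 h from 2187 to 3726 (without infant 24 h female1 2187, 24 h male2 2202, 0 h female2 2225) and at 48 h from 3260 to 4844. Sex in adults ran from 6948 to 8095. Sex in infants ran from 224 to 1444, with moves without 0 h male1 (343), male2 (1444) and female1 (240), 24 h male1 (224), female1 (301) and female2 (448), and 48 h male1 (351), female1 (356) and female2 (294). The sex difference of the time changes ran from 1556 to 3423 in adults (without 0 h female2 1556, male1 1870, female1 2047) and from 0 to 38 in infants (without 0 h male1 8, male2 38, female1 2 and female2 1, 24 h male1 3, 48 h male2 1 and female2 3). Lists passing ran from 121 to 139.

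No named gene that passed a test of 1 change reversed its direction in any setting. Over all tests 141 values of named genes no longer passed. Calls most often lost were Stab2 in adults at 48 h (24 settings), H19 in adults at 24 h (15), Mdm2 in infants at 48 h (14), Cdkn1a in infants at 24 h (10), and Birc5 in infants (10) and Ccnd1 in adults (10) from 24 to 48 h. Normexp correction shrank the changes of dim genes, at 48 h in infants to -4.68 log2 for Rhd and -6.22 for Slc4a1 and at 24 h in adults to -0.91 for Ccna2, so folds of genes near background depend on the background method. Signal near background limits any fall, so genes such as Rhd in adults can show none. With 2 mice per cell many small changes stay undetected.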

Other observations

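Hepatocyte genes rose in infant liver within 48 h. Growth was not told apart from radiation here, and most hepatocyte maturation genes were higher in adults than in infants at 0 h. Cps1 rose 3.10-fold, Cyp27a1 by 1.35 log2 and Slco1a4 3.48-fold, and of 29 hepatocyte maturation genes 19 were higher and none lower (22 adjusted over the list alone; camera adjusted p 8.03e-09, but adjusted p = 0.0859 with an estimated correlation). Bile acid genes were higher for 11 of 18 (12 adjusted over the list alone; 0.00296, but adjusted p = 0.311 with an estimated correlation), xenobiotic metabolism genes for 16 of 31, among them Cyp2c55 (5.46-fold) (17 adjusted over the list alone; 0.000628, but adjusted p = 0.366 with an estimated correlation), and fatty acid synthesis genes for 10 of 20, with Scd1 up 5.43-fold (11 adjusted over the list alone; 0.00957, but adjusted p = 0.366 with an estimated correlation). None of these lists held a lower gene. NRF2 targets were higher for 12 of 21 and lower for 1 (14 and 1 adjusted over the list alone; 0.00296, but adjusted p = 0.311 with an estimated correlation), with Gstm2 (log2 1.45) among them, and heat shock genes for 6 of 14 (7 adjusted over the list alone; 0.0343, but adjusted p = 0.459 with an estimated correlation).

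Other infant programmes at 48 h were quieter or fell. Fetal liver genes were lower for 4 of 16, none higher (4 adjusted over the list alone; camera adjusted p 0.000503, but adjusted p = 0.0523 with an estimated correlation). Fatty acid oxidation and PPARA targets gave 1 higher and 9 lower of 28, with Cyp4a10 at log2 -1.35 (1 and 9 adjusted over the list alone; 0.000251, but adjusted p = 0.311 with an estimated correlation). Cholesterol synthesis gave 2 higher and 3 lower of 24 (adjusted p 0.151), gluconeogenesis 4 and 1 of 12 (0.733), the unfolded protein response 4 and 1 of 21 (0.733), and cholangiocyte markers 5 and 0 of 13 (0.387). Pancreatic acinar markers gave 3 and 0 of 7 (0.206) and muscle and adipose markers 0 and 0 of 6 (0.451). Imprinted genes gave 3 and 3 of 15 (0.206). In adults at 48 h NRF2 targets were higher for 4 of 21, with Nqo1 at log2 0.66 (8 adjusted over the list alone; 2.84e-05, but adjusted p = 0.314 with an estimated correlation).

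The adult comparisons may carry a time-of-day component: 15 of 18 clock genes differed between 0 h males and females within slide 3. If so, adult females sampled at the clock time of the males should lose the Dbp and Arntl differences; unirradiated mice of both sexes sampled every 4 h would settle it.

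By 48 h 19 of 26 erythroid markers in infants lay at or below the adult 0 h mean. Only 14 of 26 were well above background on all adult 0 h arrays. Blood formation in infant liver may have been reduced by radiation or by growth. Sham-irradiated littermates at the later ages would part these: growth predicts the same fall of Rhd, Slc4a1 and Mpo in them, radiation predicts none. The earlier fall of Rag1 and Vpreb1 than of Camp would follow from lymphoid precursors dying first and granulocytes ageing out, which counts of liver cells by flow cytometry at 24 and 48 h could test. A within-slide median of -3.45 log2 for erythroid genes makes slide an unlikely source. Fewer blood cells would also raise the share of hepatocyte RNA, and with it genes such as Cps1, but this was not tested.

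In adults Hbb-bt fell 122-fold at 48 h. Only 14 of 26 erythroid markers were well above background on all adult 0 h arrays. Of these 14, 6 were lower, among them the globins Hbb-bt, Hba-a1, Hba-a2 and Hbb-b1. Apart from these globins Slc4a1 changed by -1.49 log2, and the rest lay between -0.73 (Ermap) and 0.42 (Mgst3). Whether the markers nearer background fell stayed unresolved. Blood counts and perfused liver would show whether the globin RNA came from circulating cells. Scaling is an unlikely source: Hbb-bt changed by -6.74 log2 with quantile normalization and -6.72 with median scaling in the adult liver, 48 h against 0 h. The hepcidin genes Hamp and Hamp2 rose in infants as red-cell precursors vanished, which is what less erythroid demand for iron might produce. Growth might produce it too, since Hamp was 191-fold higher in adults than in infants at 0 h. Serum iron and the erythroid hormone erythroferrone, with sham-irradiated infants of the later ages, would tell.

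Which cells carried the interferon response at 24 h in adults was not tested, and sorted liver cells would show it. At 48 h the mitotic gene Birc5 fell in adult females (log2 -2.59), lay at log2 -0.29 in adult males and rose in infants, a call lost in 4 settings. Other mitotic genes differed from it. Mki67 changed by -2.51 log2 in adult females and -1.56 in adult males, and its infant mean level went from 4.49 at 0 h to 3.83 at 48 h. The median of the G2 and M list was -0.49 log2 in adult males, and in infants the list leaned neither way. Labelling of DNA synthesis together with hepatocyte stains would show which cells, if any, kept dividing.

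Afp and H19 in 1 adult male may reflect a trace of infant RNA (63.6% of 11 genes, several of them related), and a repeat array from that liver would settle it.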
